A study of Bacillus subtilis PY79 with 54 samples.

How the data were processed

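ChIP, WGS and Hi-C libraries of Bacillus subtilis PY79 strains were compared, 54 in all. Per the labels, cells had 0.5% xylose for 90 min in all samples but 4, and in the time course Spo0J was induced with 0.5 mM IPTG for 0, 15, 25 or 35 min. The labels of the anti-HBsu, anti-Rok and wild-type anti-HNS ChIP libraries and of the wild-type WGS library state no xylose. ChIP used antibodies against mCherry, HBsu, H-NS or Rok. Samples were grouped by assay, antibody, strain and time as the labels state them. Per the labels, the steady-state Hi-C strains keep 1 parS site near the origin. The anti-HBsu library was grouped by the strain code in its title, although its genotype label says wild type.

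The ChIP and WGS files hold coverage, the number of reads over each position, as whole numbers that the authors deposited without scaling, judged from the values. Reads were aligned with Bowtie2 2.1.0, per the submitters' processing notes, and the reference build is not given in the sources used here. Of the 22 files, 4 had 363 to 673 positions more than the 4033459 of the rest, and their positions were rescaled linearly to that length. The Hi-C files hold a contact signal that the authors deposited as a symmetric matrix of 404 bins of about 10 kb. Its rows sum to 0.997 to 1.002, so each bin was scaled to an equal total before deposit. The balancing method and read filters are not given in the sources used here. The diagonal holds 0, as do the cells next to it apart from the corner that joins the ends of the chromosome, so distances start at 2 bins (20 kb) and not at the 1 bin planned. No 2 matrices were identical.

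Mean coverage was 13.7 to 101.8 in the 12 ChIP libraries, lowest in wild-type anti-HNS, and 42.4 to 73.5 in the 10 WGS libraries. Hi-C depth is unknown, so no counting error was attached to contacts. Intervals on shares of bins are 95% Wilson intervals. They cover counting error only and treat neighbouring bins as independent, which they are not.

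ChIP and WGS coverage were each divided by their genome mean and averaged in bins of 1000 positions, and the log2 ratio of ChIP to the WGS of the same strain was taken. Bins with WGS under 0.25 of the median were to be left out, and there were 0. Bins at 2-fold or more were counted, and adjacent ones joined into regions. Pearson and Spearman correlations across bins carry a jackknife SE over blocks of 100 kb. Overlaps were set against the product of the bin counts over all bins and against 4032 rotations. Copy number is the coverage of a segment over the median of 20 kb on either side. The origin to terminus ratio compares 100-kb windows around position 1 and around its antipode. Planned gene lists, gene names, AT share and the exclusion of rRNA bins were not used here because the gene table at hand belongs to another assembly. The planned copy-number check of hbs became a scan of WGS for raised segments and for gaps of at least 100 positions. The rule for named genes, the 10 highest per ChIP library with runs of neighbours merged, was applied to 1-kb bins, and the text names the highest of these. For Hi-C it took the 3 called local bins with the largest change per strain. Stretches outside that rule were named after their values were seen.

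The axis of juxtaposition was set at 4020001 to 4030000, the bin with the highest mean score in the control. The score at each half-separation (the distance from the midpoint of 2 loci to either) is the log2 of mean contact for pairs whose midpoint lies within 5 bins of the axis over the median for pairs of the same separation with midpoints 20 bins or more away from the axis and its antipode. Scores at 141 half-separations from 100 to 1500 kb were tested, and their means over 3 zones. Contact by distance used 199 separations from 20 to 2000 kb. Local contact is the mean contact between the 5 bins before and the 5 bins after each of 404 bins, over the library mean. The front is the largest half-separation reached from 50 kb outward with a 5-bin running median of at least 0.5, without a gap longer than 3 bins, and rates are least-squares slopes over 15, 25 and 35 min.

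Each of 8 strains was compared with the control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with strain as the only factor, 7 residual degrees of freedom and Benjamini-Hochberg adjustment within strain at 0.05. The 24 zone tests were adjusted together. All 16 steady-state libraries shared 1 estimate of spread, and a strain with 1 library was assumed to vary like the others. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Neighbouring positions are correlated, so counts of calls overstate the number of separate changes. All strains share the same control libraries, and no correlation of changes between strains was computed. Maps of 1 strain correlated at r = 0.861 to 0.915 after removal of the distance trend (10 pairs, median 0.883), and maps of different strains at 0.835 to 0.909 (110 pairs, median 0.88).

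Steps were tested on simulated data. Fronts were recovered without error in 8 simulated matrices, but their score ended in a sharp step, so accuracy at a graded edge was not tested. In simulated ChIP, 200 of 200 bins raised 4-fold were found. Of 40 local-contact bins changed by a log2 value of 0.1, limma recovered 35 in H-NS-mCherry (4 libraries), 20 in HupA-mCherry plus HupB (2 libraries) and 13 in HupA-mCherry (1 library), and at 0.2 it recovered 40, 39 and 39. Bins called without a simulated change numbered 1, 0 and 1 at 0.1, and 5, 3 and 3 at 0.2. Noise was drawn separately for each bin and library. False calls from shifts that neighbouring bins of a library share were therefore not tested.

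Designs, tests and most alternatives were fixed before the data were examined. They covered other thresholds, bands, bin sizes and normalizations, a replicate block, a variance trend, rebalanced matrices and each library left out. Alternatives added afterwards left out the 3 bins that share reads with the constructs, moved the start of the front search, set the threshold by each library's own score, held the wild-type anti-HNS ChIP constant and kept the longer files' positions as deposited. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.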

Results

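Bacillus subtilis PY79 cells that made foreign DNA-binding proteins were profiled by chromatin immunoprecipitation (ChIP), whole-genome sequencing (WGS) and Hi-C. The question, as the title of the series puts it, was whether extra nucleoid proteins affect how the SMC complex moves along the chromosome. SMC is a condensin that the ParB protein Spo0J loads at parS sites, and it draws the chromosome arms together as it travels from the origin region. The extra proteins were the HU subunits HupA and HupB of Escherichia coli, its silencing protein H-NS, and the archaeal histones HmfA and HmfB of Methanothermus fervidus. Each was made from a xylose-induced promoter, most often as a fusion to the red fluorescent protein mCherry. HBsu, the HU protein of B. subtilis, and Rok, a nucleoid protein of B. subtilis that represses genes of foreign origin, served as native counterparts.

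The 54 samples comprised 12 ChIP libraries, 10 WGS libraries and 32 Hi-C libraries. Each ChIP target and each WGS strain had 1 library, so no test between those libraries was possible. Of the Hi-C libraries, 16 came from steady-state cultures of 9 strains with 1 parS site. These were the control and HupA-mCherry plus HupB, HmfA-mCherry plus HmfB and untagged H-NS with 2 libraries each, H-NS-mCherry with 4, and HupA-mCherry, HupB-mCherry, HmfA-mCherry and HmfB-mCherry with 1 each. The other 16 formed a time course in 4 strains, with 1 library at each of 0, 15, 25 and 35 min after IPTG had switched on Spo0J. Mean coverage per position was 13.7 to 101.8 in ChIP and 42.4 to 73.5 in WGS, and the read depth of the Hi-C matrices is unknown. No gene annotation of the build behind the files was used here, so regions are given by file position on the single chromosome of 4033459 positions.

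WGS coverage separated the strains by the number of xylose constructs that their labels list. The segment at 1853601 to 1854900 was covered at 0.99 and 1.05 times its flanks in the HBsu-mCherry strain and the wild type, which have no such construct. It reached 2.5 to 2.86 in the 6 strains with 1 construct, and 4.2 in HupA-mCherry plus HupB and 4.28 in HmfA-mCherry plus HmfB, which carry 2. These same 2 strains lacked 723 positions near 3020346 in WGS. The HBsu-mCherry strain had a segment at 2203401 to 2204000 at 3.09 times its flanks, against 0.99 to 1.14 in the other strains, and lacked positions 3720580 to 3720857. The anti-HBsu ChIP library is described as wild type in its genotype label, but its title carries the code of the HBsu-mCherry strain, and it lacked positions 3720718 to 3720857. Coverage near the origin exceeded that near the terminus in all 10 WGS libraries, by 2.84-fold (SE 0.021 over 10-kb bins) in the wild type, 2.81 in the HBsu-mCherry strain and 2.73 in untagged H-NS. The ratio was 2.33 (SE 0.03) in H-NS-mCherry and 2.49 to 2.58 in the 6 strains with HU or histone constructs. With 1 culture per strain these ratios have no replicate check, and the label of the wild type alone states no xylose.

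H-NS and Rok lay on many of the same stretches of the chromosome. H-NS-mCherry was enriched at least 2-fold over WGS in 202 of 4033 bins of 1 kb (5.01%, 95% Wilson interval 4.38 to 5.73%), untagged H-NS in 181 (4.49%, 3.89 to 5.17%) and Rok in 195 (4.84%, 4.22 to 5.54%). The H-NS libraries, made with different antibodies, shared 164 of these bins, where independent positions would share 9.1. H-NS-mCherry and Rok shared 106 (9.8 by chance), and untagged H-NS and Rok shared 98 (8.8 by chance). At the Rok-bound bins the H-NS-mCherry signal was 2.73-fold higher than elsewhere and that of untagged H-NS 1.99-fold higher. No rotation of the bins around the chromosome, of 4032, gave as large a difference for either. Over all bins, H-NS-mCherry correlated with untagged H-NS at r = 0.80 (jackknife SE 0.06, rho = 0.47) and with Rok at r = 0.65 (SE 0.039, rho = 0.44). These are the libraries' values across bins, which are not replicates, and the Rok library came from wild-type cells whose label states no xylose.

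The enriched bins formed 64 regions in H-NS-mCherry, 48 in untagged H-NS and 78 in Rok. Of the 64, 15 (27 bins) had a mean below 0 in untagged H-NS, and 13 of these had 0.65 to 1.20 in the wild-type anti-HNS library, whose cells make no H-NS, so H-NS-mCherry enrichment there cannot be read as binding by H-NS. The longest in each spanned 18 kb, at 2007001 to 2025000 for both H-NS libraries and at 2006001 to 2024000 for Rok. Mean enrichment (log2) over the H-NS stretch was 2.24 in H-NS-mCherry, 1.87 in untagged H-NS and 1.72 in Rok. Another H-NS region of 11 kb, at 1844001 to 1855000, had means of 2.06 and 1.80, with 1.02 in Rok. A Rok region of 14 kb at 3940001 to 3954000 averaged 3.16 in Rok and 1.51 in H-NS-mCherry. The highest Rok bin, 3992001 to 3993000, reached 23.6-fold. Sites also separated: 1 of the highest Rok bins, at 252001 to 253000, had 4.22 in Rok but -0.34 in H-NS-mCherry and -0.61 in untagged H-NS.

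**Figure D1:**
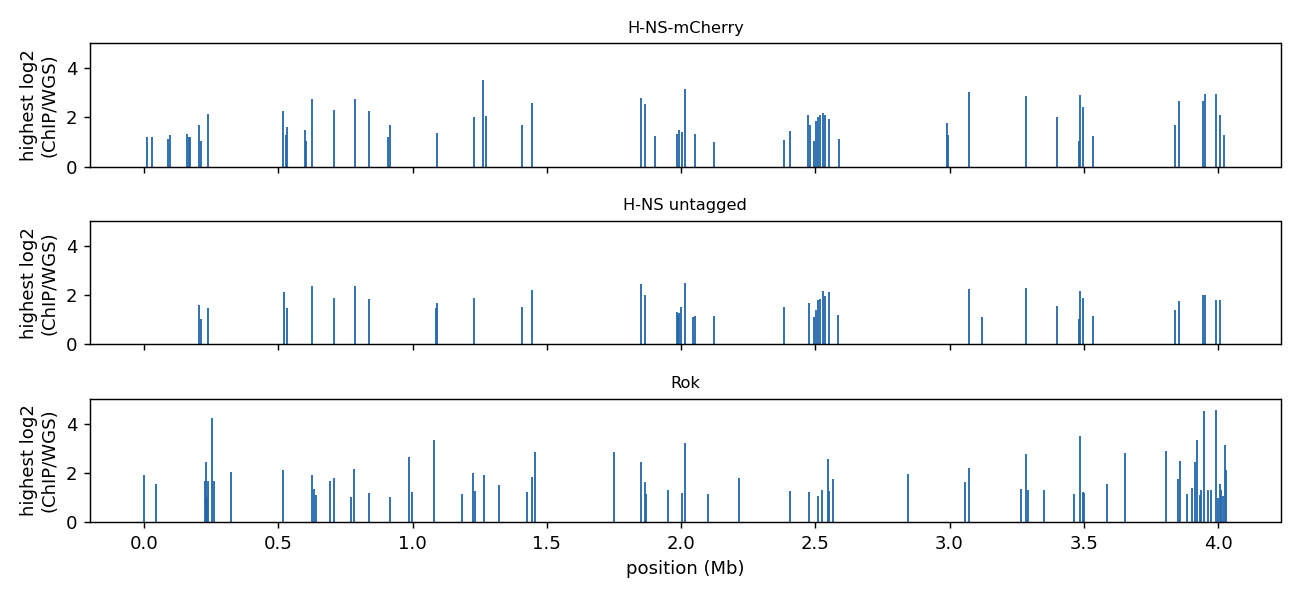
Regions enriched at least 2-fold over WGS along the chromosome (x axis, position in Mb), each drawn as a line whose height is its highest 1-kb bin (y axis, log2 of ChIP over WGS), for H-NS-mCherry (64 regions), untagged H-NS (48) and Rok (78). Many positions recur in the 3 panels, such as 2007001 to 2025000, while 252001 to 253000 stands out in Rok alone.

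The archaeal histones were low where H-NS was high. At the Rok-bound bins, HmfA-mCherry was at 0.51 times its level elsewhere, HmfB-mCherry at 0.47 and HmfA-mCherry plus HmfB at 0.50, and at H-NS-mCherry-bound bins they were at 0.45, 0.40 and 0.43. At the 89 Rok-bound bins without H-NS-mCherry they were only at 0.85, 0.83 and 0.85 (169, 35 and 52 of 4032 rotations as large), and at the 96 H-NS-mCherry-bound bins without Rok at 0.63, 0.55 and 0.60 (0 rotations as large). Of these 96 bins 27.1%, and of all 202 H-NS-mCherry-bound bins 13.9%, were below 0 in untagged H-NS. Both sets include bins of the regions above that cannot be read as binding by H-NS. Values at these bins, here and for wild-type anti-HNS below, therefore do not describe H-NS sites alone. HmfA-mCherry was raised at least 2-fold in 133 bins and lowered in 347, HmfB-mCherry in 42 and 224, and HmfA-mCherry plus HmfB in 17 and 216. The 3 histone profiles correlated with each other at r = 0.90 to 0.95. The highest bin of HmfA-mCherry and of HmfA-mCherry plus HmfB was 1932001 to 1933000, with log2 values of 1.96 and 1.38 (1.24 in HmfB-mCherry), and that of HmfB-mCherry was 758001 to 759000, with 1.91. HmfA-mCherry plus HmfB correlated with Rok at r = -0.53 (SE 0.044), and without division by WGS the sign turned, to 0.17. The anti-HNS library from wild-type cells, which make no H-NS, was itself low at Rok-bound bins (0.69-fold), at H-NS-mCherry-bound bins (0.67-fold) and at those of them without Rok (0.83-fold), and it correlated with HmfA-mCherry plus HmfB at r = 0.73. Given that library, the partial correlation with Rok was -0.35 (SE 0.031) in HmfA-mCherry plus HmfB, -0.35 (SE 0.029) in HmfB-mCherry and -0.17 (SE 0.025) in HmfA-mCherry. The partial correlation with H-NS-mCherry, computed after the other values were seen, was -0.408 (SE 0.03), -0.415 (SE 0.031) and -0.151 (SE 0.02) in the same order, against -0.592, -0.594 and -0.434 without that step.

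HBsu and the E. coli HU proteins varied less over the chromosome than the other proteins. The standard deviation of log2 enrichment over bins was 0.21 for HBsu and 0.23 to 0.24 for the 3 HupA and HupB libraries, against 0.58 for H-NS-mCherry, 0.65 for HmfA-mCherry and 0.69 for Rok. It was 0.32 in wild-type anti-HNS, the library without a target and with the lowest coverage. At least 2-fold enrichment was found in 1 bin for HBsu, 7 for HBsu-mCherry, 14 for HupA-mCherry, 16 for HupB-mCherry and 7 for HupA-mCherry plus HupB. Some of these bins were as high without a target: 598001 to 599000 had 1.27, 1.25 and 1.20 in the HU libraries and 1.24 in wild-type anti-HNS, and 915001 to 916000 had 1.30, 1.15 and 1.36 against 1.39. The HBsu bin, 1085001 to 1086000, had a log2 value of 1.33, and the same bin had 1.96 in HBsu-mCherry and 1.98, 1.17 and 1.92 in the HU libraries, against -0.40 in H-NS-mCherry. HBsu correlated with HupA-mCherry plus HupB at r = 0.67 (SE 0.046) and with HBsu-mCherry at r = 0.73 (SE 0.048). HBsu and wild-type anti-HNS correlated at r = 0.58 (SE 0.055), so part of such values is shared with a library that had no target. At Rok-bound bins HBsu was at 0.79 times its level elsewhere and the HU libraries at 0.78 to 0.81, but wild-type anti-HNS was lower still (0.69). At the 89 Rok-bound bins without H-NS-mCherry, HBsu was at 0.93 (104 of 4032 rotations as large), HBsu-mCherry at 0.97 (1688) and each HU library at 0.95 (226 to 381), so a loss at Rok sites as such was not shown. The bin 1263001 to 1264000 was high in 5 anti-mCherry libraries, at 3.52 in H-NS-mCherry, 2.36 in HBsu-mCherry and 2.78, 2.63 and 2.0 in the HU libraries. It was at -0.19 in untagged H-NS, 0.45 in HBsu and -0.20 in wild-type anti-HNS.

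In steady-state cells the arms were aligned along almost the whole chromosome in every strain. The juxtaposition score, the log2 excess of contact between loci facing each other across the axis at 4020001 to 4030000, stayed above 0.5 out to 1940 to 1960 kb from that axis in all 16 libraries. The mean score at 500 to 1000 kb was 1.58 ± 0.049 (SD, n = 2) in the control, a 3.00-fold excess. It was 1.55 ± 0.038 (SD, n = 2) in HupA-mCherry plus HupB and 1.55 ± 0.006 (SD, n = 2) in HmfA-mCherry plus HmfB. In limma, 0 of 141 positions differed from the control in HupA-mCherry plus HupB (0 at an unadjusted p under 0.05) and 0 in HmfA-mCherry plus HmfB (1 at an unadjusted p under 0.05). The zone changes were -0.03 (SE 0.066) and -0.04 (SE 0.066) at 500 to 1000 kb.

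Scores were higher than the control in the only library of each of 4 strains, and in untagged H-NS at 100 to 500 kb. At 500 to 1000 kb the change was 0.24 (SE 0.08) in HupA-mCherry, 0.25 (SE 0.08) in HupB-mCherry, 0.27 (SE 0.08) in HmfA-mCherry and 0.23 (SE 0.08) in HmfB-mCherry, or 1.17- to 1.20-fold, each with a limma adjusted p of 0.036. These SEs and p values come from the spread of the other strains, whose SDs ranged from 0.006 to 0.092, and no replicate of the 4 strains checks them. Untagged H-NS passed at 100 to 500 kb, with a change of 0.21 (SE 0.066, limma adjusted p = 0.036), and had 0.16 (limma adjusted p = 0.062) at 500 to 1000 kb. By position, 70 of 141 were higher in HupA-mCherry, 89 in HupB-mCherry, 99 in HmfA-mCherry, 62 in HmfB-mCherry and 80 in untagged H-NS, with 0 lower. The 4 H-NS-mCherry libraries lay far apart. Replicates A to D had 1.63, 1.55, 1.75 and 1.73 at 500 to 1000 kb (SD 0.092), and 1.44, 1.38, 1.62 and 1.58 at 100 to 500 kb, where the control had 1.37 and 1.42 and untagged H-NS 1.63 and 1.57. Contact at 20 to 50 kb (log2) was 2.002, 1.965, 2.169 and 2.154 in replicates A to D, 2.001 and 2.044 in the control and 2.152 and 2.131 in untagged H-NS. The mean change in H-NS-mCherry score at 500 to 1000 kb was 0.08 (SE 0.057), and limma called 0 of 141 positions (23 at an unadjusted p under 0.05).

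These calls rest on single libraries. Without control replicate A the counts were 2 in HmfA-mCherry and 0 in HupA-mCherry, HupB-mCherry, HmfB-mCherry and untagged H-NS, and the changes at 500 to 1000 kb in HupA-mCherry (0.20), HmfB-mCherry (0.19) and untagged H-NS (0.12) lost the unadjusted limma p under 0.05 that they had with all libraries. Without untagged H-NS replicate A its count was 0 and its change at 100 to 500 kb (0.18) lost the unadjusted p under 0.05, and without replicate B the count was 16. Without H-NS-mCherry replicate B, 68 positions were called in H-NS-mCherry, and its changes of 0.15 at 100 to 500 kb and 0.12 at 500 to 1000 kb passed at an unadjusted p under 0.05, as did 0.13 at 100 to 500 kb without replicate A.

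**Figure D2:**
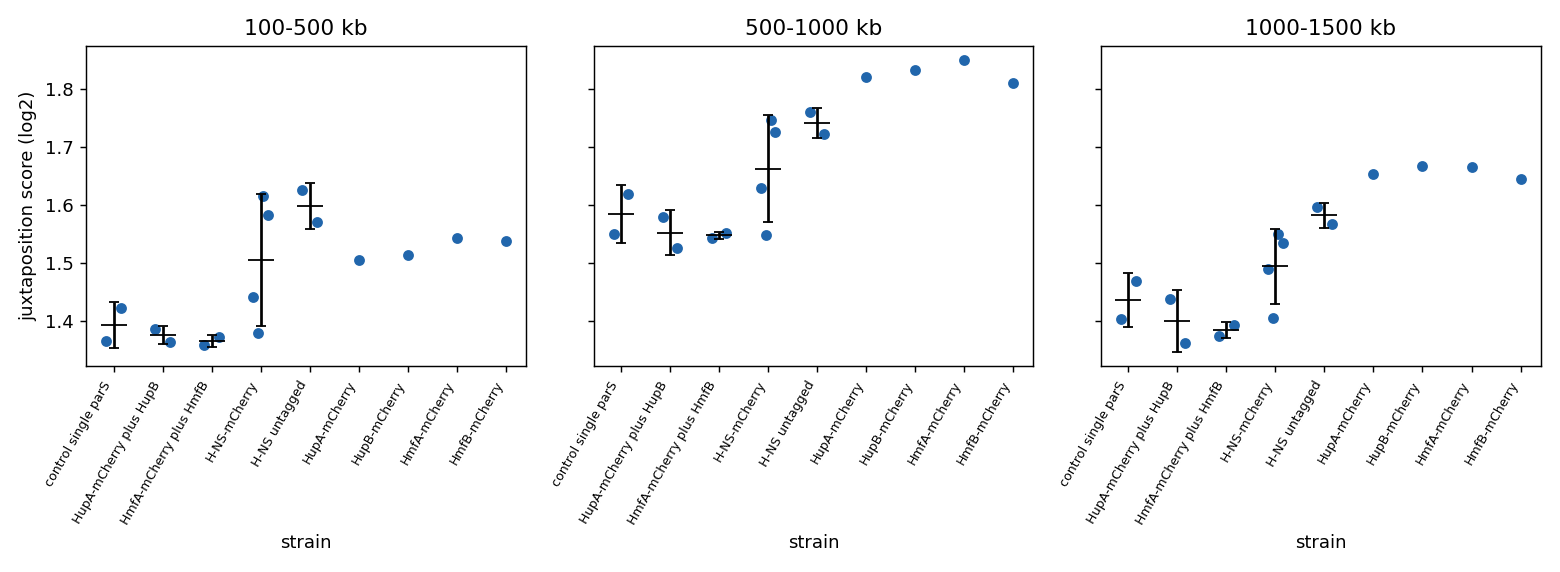
Mean juxtaposition score (y axis, log2) of each steady-state Hi-C library (points, spread sideways for display) by strain (x axis) at 100 to 500, 500 to 1000 and 1000 to 1500 kb from the axis, with lines at the mean and bars of 1 SD where a strain had more than 1 library. At 500 to 1000 kb the 4 strains with 1 library lay at 1.81 to 1.85, and the control at 1.55 and 1.62.

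Calls of contact at given distances depended on the fit. Of 199 separations from 20 to 2000 kb, limma called 14 in HupA-mCherry (13 higher and 1 lower) and 35 in HupB-mCherry (30 higher and 5 lower), with changes between -0.11 and 0.11. It called 0 in the other 6 strains, where the counts at an unadjusted p under 0.05 were 0 in HupA-mCherry plus HupB, 1 in H-NS-mCherry, 60 in HmfA-mCherry, 39 in HmfB-mCherry, 0 in HmfA-mCherry plus HmfB and 9 in untagged H-NS. Mean contact at 100 to 300 kb (log2 over the average) was 0.81 in the control, 0.88 in HupA-mCherry, 0.89 in HupB-mCherry, 0.88 in HmfA-mCherry and 0.87 in HmfB-mCherry, so a rise particular to the HU strains was not shown. Without control replicate A, 0 separations were called in HupA-mCherry and in HupB-mCherry, and without control replicate B 0 in HupA-mCherry. With separations from 3 bins, HupA-mCherry had 0, and with a trend in the variance it had 33, HmfA-mCherry 33 and HmfB-mCherry 24. With the replicate letter as a block the counts were 99 in HupA-mCherry, 125 in HupB-mCherry, 120 in HmfA-mCherry, 92 in HmfB-mCherry, 45 in untagged H-NS and 1 in H-NS-mCherry, although the letters did not pair the libraries.

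Local contact was on average lower at H-NS-bound bins in the H-NS strains, although stretches with and without H-NS moved in both directions. Contact between the 5 bins of 10 kb on either side of 3960001 to 3970000 fell by 0.21 (log2, SE 0.03, limma adjusted p = 0.0005) in H-NS-mCherry and by 0.25 (SE 0.03, limma adjusted p = 0.00014) in untagged H-NS. That bin itself held no region enriched 2-fold in either H-NS library. It lay between the H-NS-mCherry regions at 3948001 to 3953000 and 3990001 to 3995000, which fall within the 5 bins on either side. At 1870001 to 1880000, beside the 11-kb H-NS region, contact fell by 0.16 (limma adjusted p = 0.0081) and 0.26 (limma adjusted p = 0.00019). At 2020001 to 2030000, which overlaps the 18-kb region, H-NS-mCherry fell by 0.10 (limma adjusted p = 0.047), and untagged H-NS was lower over 1830001 to 2060000. Other stretches that fell in untagged H-NS were 2480001 to 2530000 (-0.17 at the strongest bin) and 3430001 to 3520000 (-0.18). Of the called stretches in untagged H-NS, 4 of 11 that fell and 1 of 13 that rose held a 10-kb bin with at least 2-fold H-NS-mCherry ChIP, and in H-NS-mCherry 3 of 3 that fell. The riser was 700001 to 720000 (0.08), and 3540001 to 3560000 fell (-0.11) without such a bin. Untagged H-NS regions at 3493001 to 3503000 and 3531001 to 3534000 lay within the 5 bins before its strongest bin. At 930001 to 940000 contact fell (-0.07) with no untagged H-NS region there or within the 5 bins on either side. Other stretches that rose were 360001 to 470000 (0.14) and 2790001 to 2940000 (0.13). Averages over 10 kb miss shorter regions enriched 2-fold in both H-NS libraries. In untagged H-NS such regions also lay in the falling stretches 190001 to 220000, 1360001 to 1430000, 2480001 to 2530000 and 2560001 to 2600000. Of its stretches that rose, only 700001 to 720000 held such a region. Over the 10% of bins with the highest H-NS-mCherry ChIP (40 of 403), the mean change minus that of the other bins was -0.037 in H-NS-mCherry (1 of 402 rotations of the bins as low) and -0.084 in untagged H-NS (2 of 402). It was -0.01 in HupA-mCherry plus HupB (21 of 402) and 0.004 in HmfA-mCherry plus HmfB (290 of 402).

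The xylose constructs left their own mark on these maps. The bin 1850001 to 1860000, which holds the segment shared with the constructs, gained contact with 980001 to 990000, at 0.0183 to 0.0412 in 14 libraries with 1 construct and 0.0162 to 0.0277 in 12 with 2, against 0.0011 to 0.0017 in the 6 control libraries. Contact with 3020001 to 3030000 was 0.0128 to 0.019 in the libraries with 2 constructs, and at most 0.002 in the others. The local values above therefore leave those 3 bins out, a choice made after the contacts were seen. The counts of 404 bins were then 10 in H-NS-mCherry (0 higher), 114 in untagged H-NS (50 higher, 64 lower) and 0 in HupA-mCherry plus HupB and HmfA-mCherry plus HmfB (31 and 9 at an unadjusted limma p under 0.05). With all bins, as planned, they were 18, 125, 5 and 7, and the 3 bins with the largest change in each of these strains lay between 1840001 and 1880000. At 1870001 to 1880000 HupA-mCherry plus HupB had -0.20 (limma adjusted p = 0.0023) with all bins and -0.07 (limma adjusted p = 0.69) without the 3. The differences at H-NS-bound bins were -0.042 in H-NS-mCherry and -0.089 in untagged H-NS with all bins (2 of 402 rotations each). From that fit, leaving out control replicate A gave 10 in H-NS-mCherry and 50 in untagged H-NS, leaving out control replicate B gave 9 and 77, and untagged H-NS had 44 without its replicate A and 75 without B. The 5 in HupA-mCherry plus HupB became 1 and 2 without its own replicates A and B and 0 without control replicate B. The 7 in HmfA-mCherry plus HmfB became 0 and 3 without its own replicates A and B, 3 without control replicate A and 0 without control replicate B.

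**Figure D3:**
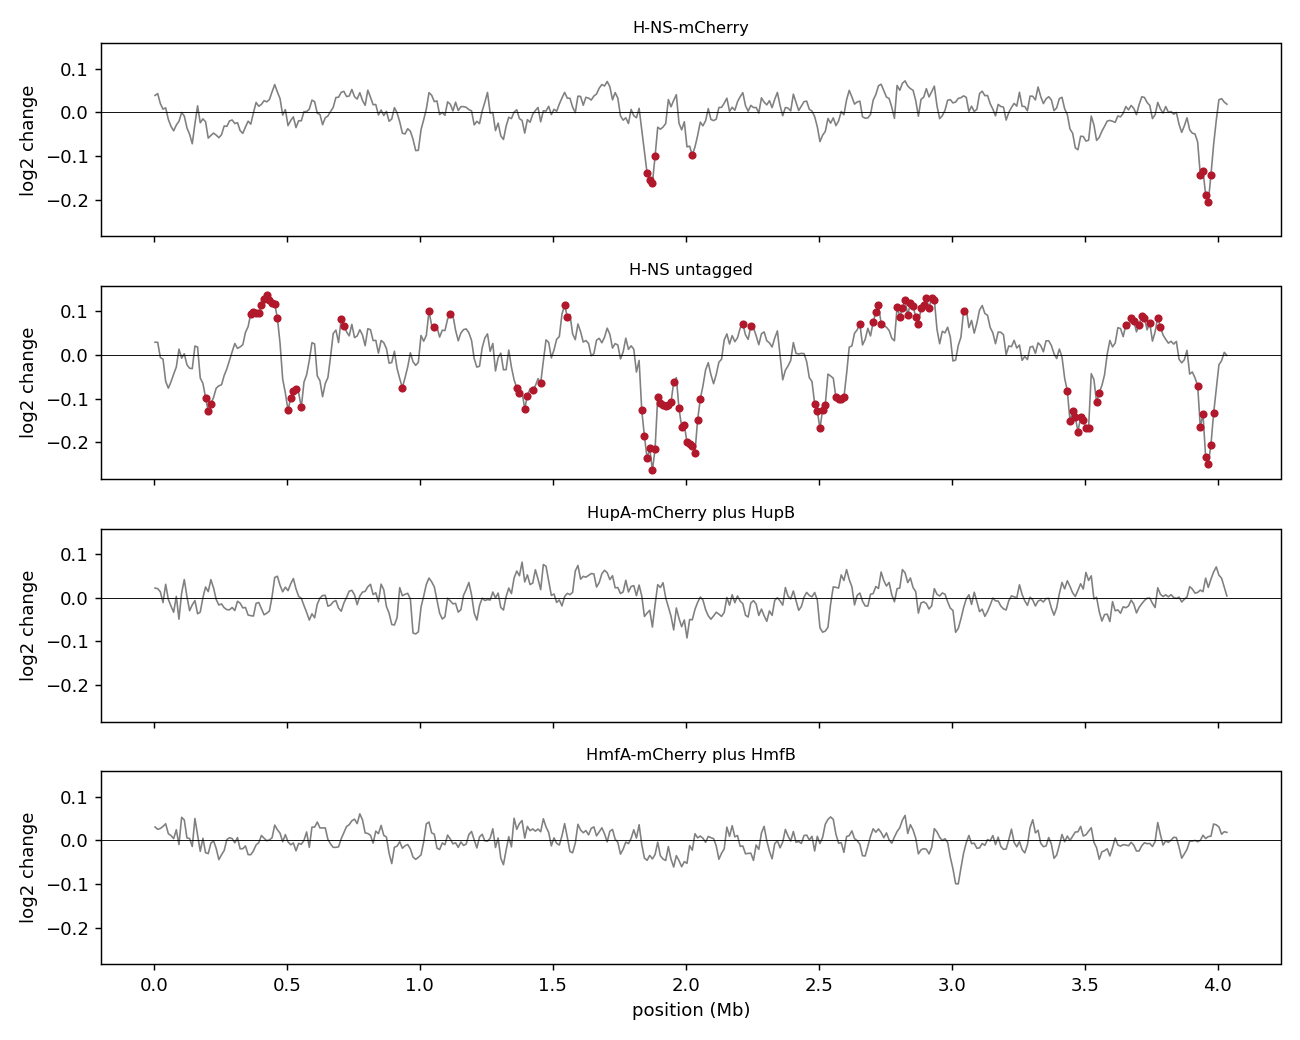
Change in local contact against the control (y axis, log2) along the chromosome (x axis, position in Mb) in H-NS-mCherry, untagged H-NS, HupA-mCherry plus HupB and HmfA-mCherry plus HmfB, with the 3 bins that share reads with the constructs left out and bins at a limma adjusted p under 0.05 as points. The H-NS strains had 10 and 114 such bins, the lowest at -0.21 and -0.26, and the other strains 0.

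Called stretches overlapped among the 4 strains with 1 library. All were compared with the same 2 control libraries, and the labels do not record sets of libraries, so overlap does not show a shared effect of the proteins. Local contact rose over 290001 to 460000 in HupA-mCherry and HupB-mCherry, 280001 to 460000 in HmfA-mCherry and 300001 to 460000 in HmfB-mCherry, with strongest bins of 0.20, 0.20, 0.22 and 0.24, and untagged H-NS rose over 360001 to 470000 as well. Against the same controls, the highest change at any bin was 0.081 in HupA-mCherry plus HupB, 0.061 in HmfA-mCherry plus HmfB and 0.072 in H-NS-mCherry. These values, with the construct bins left out, argue against the controls alone as the source of the rise. Local contact fell over 640001 to 670000 in each of the 4 strains with 1 library, by 0.17, 0.19, 0.15 and 0.15 at the strongest bin. With the construct bins left out, limma called 40, 68, 45 and 54 of 404 bins. With all bins the counts were 37, 63, 44 and 47, which fell to 4, 28, 17 and 32 without control replicate A and to 8, 29, 21 and 26 without control replicate B.

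In the time course, juxtaposition spread from the axis at nearly equal speed in the 4 strains. No library had a front before IPTG. In the control the front stood 540, 1130 and 1630 kb from the axis at 15, 25 and 35 min, a rate of 54.5 ± 2.6 (SE of the slope) kb per min. The rate was 54.0 ± 2.31 (SE) kb per min in HupA-mCherry plus HupB and in HmfA-mCherry plus HmfB and 53.5 ± 2.02 (SE) in H-NS-mCherry, or 0.991, 0.991 and 0.982 of the control. The differences were smaller than the SE of each slope. Those SEs come from a bend over time that all strains shared, so they do not measure whether the rates differ. With 1 library per time no test between strains was made.

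At each time the fronts of the 3 strains with extra proteins were further out than that of the control. HupA-mCherry plus HupB stood at 600, 1180 and 1680 kb, HmfA-mCherry plus HmfB at 630, 1210 and 1710 kb, and H-NS-mCherry at 620, 1190 and 1690 kb. The mean lead over the control was 53.3 ± 5.8, 83.3 ± 5.8 and 66.7 ± 11.5 kb (SD over 3 times). Fitted lines met 0 kb at 4.82 min in the control and at 3.64, 3.09 and 3.19 min in these strains. At a score threshold of 0.3 in place of 0.5, the leads were 220, 226.7 and 183.3 kb, and at 0.75, searched from 150 kb, that of H-NS-mCherry was 36.7 kb.

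**Figure D4:**
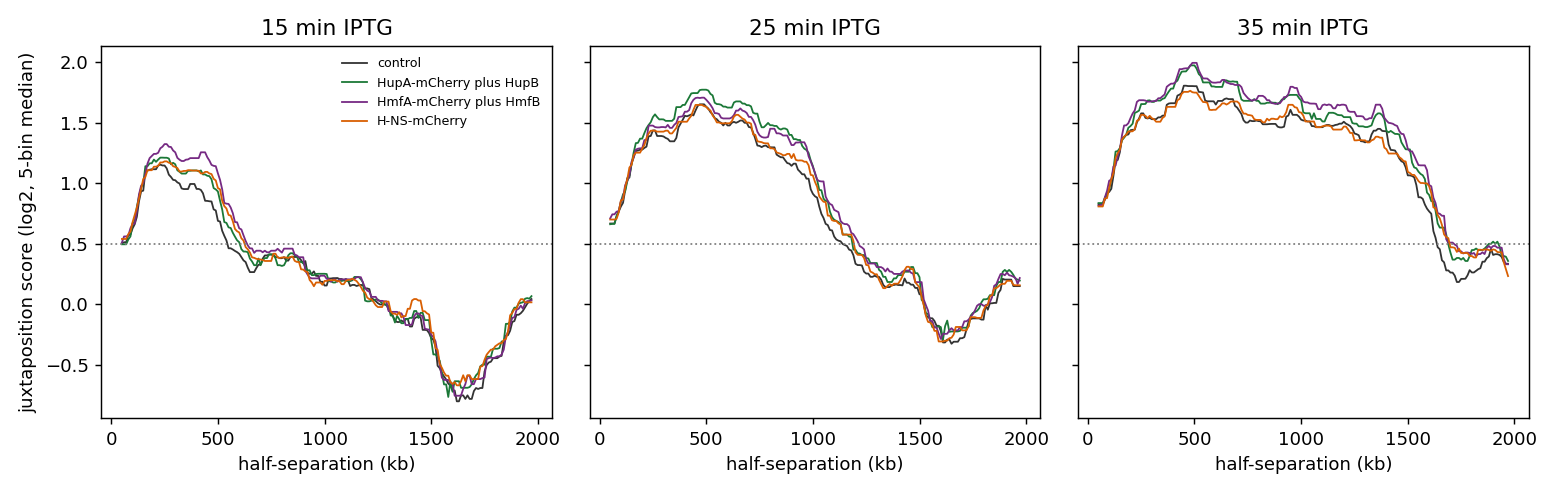
Juxtaposition score (y axis, log2, running median of 5 bins) by distance from the axis (x axis, half-separation in kb) at 15, 25 and 35 min of IPTG in 4 strains (lines), with the 0.5 threshold dotted. The falling edge moved from 540 to 1630 kb in the control and from 630 to 1710 kb in HmfA-mCherry plus HmfB.

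**Figure D5:**
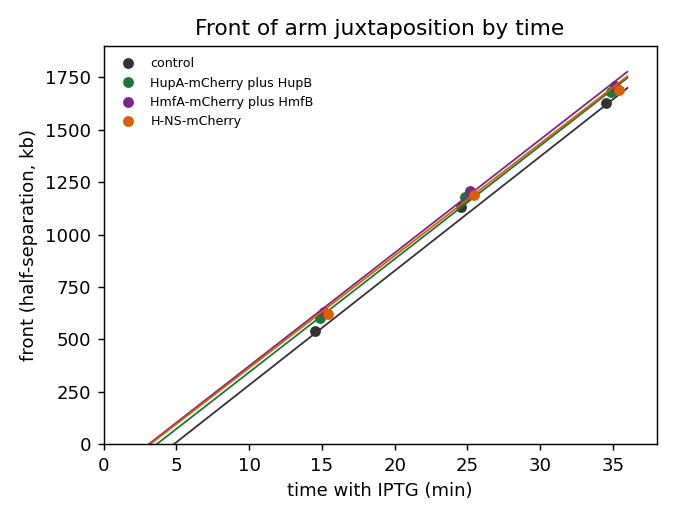
Front of arm juxtaposition (y axis, kb from the axis) by time with IPTG (x axis, min) in 4 strains, with 1 library per point, points at 15, 25 and 35 min spread sideways for display, and least-squares lines. The slopes were 53.5 to 54.5 kb per min, and the fronts of the 3 strains with extra proteins lay 50 to 90 kb beyond the control.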

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

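The limma test of separations at steady state was fixed before the data were examined, and all other comparisons in this part were chosen after the results were seen. Contact by distance differed from the control in the time course of the strains with 2 constructs. At 20 to 50 kb it also differed in H-NS-mCherry, in the opposite direction. No such changes were shown at steady state. In the time course, HupA-mCherry plus HupB exceeded the control of the same time by 0.095 (log2) at 20 to 50 kb and by 0.069 at 100 to 300 kb, and lay at -0.064 at 1000 to 2000 kb. HmfA-mCherry plus HmfB had 0.095, 0.06 and -0.061. At steady state limma called 0 of 199 separations in either strain (0 at an unadjusted p under 0.05). The differences there were -0.01, -0.009 and 0.012 in HupA-mCherry plus HupB and -0.014, -0.023 and 0.018 in HmfA-mCherry plus HmfB, near the SD of the control (0.03, 0.018 and 0.018). Their sign was opposite to the time course in both libraries in all cases except HmfA-mCherry plus HmfB at 20 to 50 kb (-0.034 and 0.006), but differences of this size do not show a direction. H-NS-mCherry differed at 20 to 50 kb by -0.073 (SD 0.013 over 4 libraries, -0.085 to -0.054) in the time course. At steady state its mean difference was 0.05, but its 4 libraries ranged from -0.057 to 0.147. At 100 to 300 and 1000 to 2000 kb its time-course values were -0.003 and 0.011. The difference between the experiments was not tested.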

How the results depend on the processing

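Among the alternatives here, those with the construct bins left out, with the 0.75 threshold searched from 150 kb, with the threshold at 0.5 of each library's own score, given the wild-type anti-HNS ChIP, and with positions as deposited were chosen after the results were seen. Leaving out single libraries aside, direction and side of the threshold held for 94 of 96 zone scores, 45 of 48 juxtaposition counts stayed within 1.5-fold, and the 6 alternatives for H-NS-bound bins gave -0.031 to -0.105. Where values moved, the cause was not tested. Hi-C depth is unknown, and the lowest ChIP coverage was 13.7, in wild-type anti-HNS. Gene lists, AT-matched lists and the exclusion of rRNA bins were not run, and a threshold of 0.75 searched from 50 kb or midpoints within 10 bins put the front at 0 in some libraries and gave no rate.

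Replicate letters did not pair the steady-state libraries: of 10 pairs of strains, 3, 4 and 4 correlated above 0.1 in juxtaposition, distance and local contact, with lowest values of -0.09, -0.69 and -0.25. Letters C and D occur only in H-NS-mCherry, so a block for the letter fits those libraries exactly and takes them out of the spread of every strain. Residual degrees of freedom fell from 7 to 4, and the median SE of juxtaposition in untagged H-NS fell from 0.073 to 0.052. With the letter as a replicate block, juxtaposition counts were 113 in HupA-mCherry, 108 in HmfB-mCherry and 124 in untagged H-NS. Distance counts were 99 in HupA-mCherry, 125 in HupB-mCherry, 1 in H-NS-mCherry, 120 in HmfA-mCherry, 92 in HmfB-mCherry and 45 in untagged H-NS. Local counts with the block were 59 in HupA-mCherry, 8 in HupA-mCherry plus HupB, 73 in HmfB-mCherry and 197 in untagged H-NS, and the zone changes at 100 to 500 kb of 0.14 in HmfA-mCherry and HmfB-mCherry passed. In H-NS-mCherry, whose replicates C and D have no control library of their letter, the block took the zone changes from 0.11, 0.08 and 0.06 to 0.02, 0 and 0.01. The block changed no other call of a zone score and moved no other count by over 1.5 times.

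With eBayes trend, distance counts were 33 in HupA-mCherry, 33 in HmfA-mCherry and 24 in HmfB-mCherry, and from 3 bins 0 in HupA-mCherry. With 10 bins on either side, local counts were 82 in HupA-mCherry, 40 in H-NS-mCherry, 74 in HmfB-mCherry and 191 in untagged H-NS. With construct bins left out they were 0 in HupA-mCherry plus HupB, 10 in H-NS-mCherry and 0 in HmfA-mCherry plus HmfB.

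Leaving out 1 library at a time gave these ranges. Juxtaposition counts were 0 to 71 in untagged H-NS, 0 to 68 in H-NS-mCherry, 2 to 93 in HmfA-mCherry, 0 to 61 in HmfB-mCherry, 0 to 62 in HupA-mCherry, 0 to 85 in HupB-mCherry, and 0 to 0 in the strains with 2 constructs. Distance counts were 0 to 0 in HupA-mCherry and 0 to 24 in HupB-mCherry. Local counts were 44 to 77 in untagged H-NS, 9 to 23 in H-NS-mCherry, 17 to 21 in HmfA-mCherry, 0 to 3 in HmfA-mCherry plus HmfB, 26 to 32 in HmfB-mCherry, 4 to 8 in HupA-mCherry, 0 to 5 in HupA-mCherry plus HupB and 28 to 29 in HupB-mCherry. Zone changes were 0.18 to 0.23, 0.12 to 0.19 and 0.11 to 0.18 (100 to 500, 500 to 1000 and 1000 to 1500 kb) in untagged H-NS, 0.07 to 0.15, 0.04 to 0.12 and 0.03 to 0.09 in H-NS-mCherry, and 0.08 to 0.14, 0.20 to 0.27 and 0.18 to 0.25 in HupA-mCherry. They were 0.09 to 0.15, 0.21 to 0.28 and 0.20 to 0.26 in HupB-mCherry, 0.12 to 0.18, 0.23 to 0.30 and 0.20 to 0.26 in HmfA-mCherry, and 0.12 to 0.17, 0.19 to 0.26 and 0.18 to 0.24 in HmfB-mCherry. Without control replicate A, 8 changes past an unadjusted p under 0.05 no longer passed.

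At threshold 0.3 the control rate was 51.5 kb per min and the leads of HupA-mCherry plus HupB, HmfA-mCherry plus HmfB and H-NS-mCherry were 220, 226.7 and 183.3 kb. With midpoints within 3 bins the leads of HupA-mCherry plus HupB and HmfA-mCherry plus HmfB were 40 and 66.7 kb. Minus the 0-min library, rates were 71.0 in the control, 69.0 in HupA-mCherry plus HupB, 67.5 in HmfA-mCherry plus HmfB and 68.0 in H-NS-mCherry, with a lead of 40 kb in HupA-mCherry plus HupB. From 150 kb at 0.75 the leads were 36.7, 70.0 and 36.7 kb, and at 0.5 of each library's own score 40 and 73.3 kb in HupA-mCherry plus HupB and HmfA-mCherry plus HmfB.

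With 200 kb windows the origin to terminus ratios were 2.65 in the HBsu-mCherry strain, 2.19 in H-NS-mCherry, 2.34 in HupA-mCherry, 2.38 in HupB-mCherry, 2.39 in HupA-mCherry plus HupB, 2.40 in HmfA-mCherry, 2.39 in HmfB-mCherry, 2.31 in HmfA-mCherry plus HmfB, 2.69 in the wild type and 2.57 in untagged H-NS. With median coverage the wild type had 2.88.

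In 5-kb bins the SD of log2 enrichment was 0.17 in HBsu, 0.17 in HBsu-mCherry, 0.19 in HupA-mCherry, 0.18 in HupB-mCherry, 0.18 in HupA-mCherry plus HupB, 0.48 in HmfA-mCherry, 0.40 in HmfB-mCherry, 0.37 in HmfA-mCherry plus HmfB and 0.24 in wild-type anti-HNS. Not divided by WGS it was 0.48, 0.50, 0.48, 0.48, 0.46, 0.78, 0.65, 0.61 and 0.58 in these, 0.72 in H-NS-mCherry, 0.90 in Rok and 0.55 in untagged H-NS. Not divided by WGS, correlations with Rok were 0.79 for H-NS-mCherry, 0.80 for untagged H-NS and 0.17 (reversed) for HmfA-mCherry plus HmfB, and those of HBsu were 0.92 with HupA-mCherry plus HupB and 0.95 with HBsu-mCherry. Given the wild-type anti-HNS ChIP these 5 were 0.57, 0.43, -0.35, 0.44 and 0.57. With wild-type anti-HNS itself, HupA-mCherry plus HupB had 0.82 in 5-kb bins and 0.91 not divided by WGS, and HmfA-mCherry plus HmfB 0.82 and 0.86.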

Other observations

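Of the tests in this part, those of the H-NS-bound stretch and of the score behind the front had been written before their results were seen, and all others afterwards.

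Contacts in the time course differed from the control in ways the fronts do not show. A limma fit of strain and time over the 16 libraries (9 residual degrees of freedom) called 178 of 199 separations in HupA-mCherry plus HupB (34 higher and 144 lower) and 162 in HmfA-mCherry plus HmfB (31 higher and 131 lower), and 2 in H-NS-mCherry. In HupA-mCherry plus HupB all 4 separations at 20 to 50 kb were higher, by 0.09 to 0.10, and all 101 at 1000 to 2000 kb were lower. In HmfA-mCherry plus HmfB the same 4 were higher and 100 of 101 lower. In H-NS-mCherry the changes at the 4 separations of 20 to 50 kb were -0.10 to -0.05, opposite to those 2 strains. Limma called 1 of these 4, and all 4 had an unadjusted p under 0.05, as had 26 of all 199. Local contact, with the construct bins left out, was called at 204 of 404 bins in H-NS-mCherry (119 higher and 85 lower), 69 in HupA-mCherry plus HupB and 44 in HmfA-mCherry plus HmfB. In H-NS-mCherry the lowest stretch, 3930001 to 3990000, had -0.21 at its strongest bin (SE 0.02, limma adjusted p = 3.7e-11), and 1690001 to 1910000 and 2000001 to 2090000 were also lower, with -0.14 and -0.12. Bound stretches also rose: 550001 to 890000 had 0.12 (limma adjusted p = 1.3e-06), 3070001 to 3170000 had 0.10 and 3280001 to 3400000 had 0.07, and a 10-kb bin with at least 2-fold H-NS-mCherry ChIP lay in 5 of 20 stretches that rose and 5 of 12 that fell. Of the 5 that rose, 1 to 130000 held only H-NS-mCherry regions with means of -0.566 to -0.435 in untagged H-NS. Enrichment there cannot be read as binding by H-NS. Shorter regions, missed by averages over 10 kb, also lay in 1220001 to 1270000 and 2350001 to 2390000, which fell. They were enriched 2-fold in both H-NS libraries, and no further stretch that rose held such a region. A stretch at 1600001 to 1660000 was lower in all 3 strains, with -0.15 in HupA-mCherry plus HupB, -0.14 in HmfA-mCherry plus HmfB and -0.18 in H-NS-mCherry. The 3 strains share the control libraries, and libraries of 1 time course may share a culture, so these adjusted p values can be too small. The difference at H-NS-bound bins in H-NS-mCherry was -0.026 here (13 of 402 rotations as low), against -0.037 at steady state with the same bins left out.

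Local contact at 1830001 to 1890000 had a mean change, with all bins, of -0.14 in HupA-mCherry plus HupB and -0.13 in HmfA-mCherry plus HmfB, which carry 2 xylose constructs. Of the strains with 1 construct, H-NS-mCherry had -0.21 and untagged H-NS -0.31, whereas HupA-mCherry, HupB-mCherry, HmfA-mCherry and HmfB-mCherry, with 1 library each, had -0.05, -0.05, -0.07 and -0.04 (0.02, 0.01, 0 and 0.04 without the construct bins, SE 0.04). Reads from the promoter copies in the constructs, placed at the native locus, are a candidate explanation for the strains with 2 constructs, since leaving out the 3 bins involved brought the change to -0.03 (SE 0.03) in each. In the H-NS strains the same step left -0.11 (SE 0.03) in H-NS-mCherry and -0.21 (SE 0.03) in untagged H-NS, and -0.13 (SE 0.02) in the time course of H-NS-mCherry. A local loss of contact where H-NS binds may add to the construct reads there, a hypothesis found in the steady-state libraries, and the time-course libraries are separate ones.

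Juxtaposition scores were higher at steady state in the 4 strains with 1 library and in untagged H-NS. The idea that HupA-mCherry or HmfA-mCherry raises the score whenever it is made is opposed at steady state by the strains that add HupB or HmfB, whose changes at 500 to 1000 kb were -0.03 and -0.04 (SE 0.066) against 0.24 and 0.27 (SE 0.08) with the fusion alone. In the time course at 35 min, with 1 library each, the same protein pairs scored 1.754 and 1.779 at 500 to 1000 kb, against 1.595 in the control. The difference between the experiments was not tested, so the idea is opposed for the steady-state libraries only. The 4 strains with 1 library rose alike, by a mean of 0.24 with an SD of 0.017 between their scores, so a difference between sets of libraries that the labels do not record may account for them. It cannot be told apart from an effect of the proteins made without their partner, because none of the 4 strains has a library in another set. For untagged H-NS no test separates a protein effect from such a set, and the doubt is real: at 100 to 500 kb its libraries had 1.63 and 1.57, next to 1.62 and 1.58 in H-NS-mCherry replicates C and D, whereas replicates A and B of that same strain had 1.44 and 1.38 and the control 1.37 and 1.42.

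Fronts lay 50 to 90 kb beyond the control in the 3 strains with extra proteins. A higher rate is opposed by the slopes, of which the highest was 0.991 of the control. A higher score behind the front could carry a fixed threshold outward. With the threshold at 0.5 of each library's own score the mean leads were 40 (SD 20), 73.3 (SD 30.6) and 56.7 kb (SD 15.3). All were above the bound of 20 kb set in advance. The prediction written before counted such leads against a higher score behind the front. A margin of the SD was added to the bound after the values were seen. HupA-mCherry plus HupB passed the bound by no more than its SD and the others by more. With that added margin the test as a whole does not decide. At 15, 25 and 35 min these leads were 40, 60 and 20 kb in HupA-mCherry plus HupB and 80, 100 and 40 kb in HmfA-mCherry plus HmfB. In H-NS-mCherry they were 70, 60 and 40 kb. Leads at fixed thresholds also changed with the threshold, as given above. An earlier start, or later sampling, also stays open: the fitted starts came 1.18, 1.73 and 1.63 min before that of the control. The SEs of these differences, 1.43, 1.44 and 1.36 min, took the errors of the strain and the control as independent. Those errors come from a bend over time that all strains shared, so the SEs do not measure the spread of the differences. Leads of 60, 50 and 50 kb in HupA-mCherry plus HupB, 90, 80 and 80 kb in HmfA-mCherry plus HmfB and 80, 60 and 60 kb in H-NS-mCherry did not grow with time.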
